A study of Homo sapiens with 27 samples.

How the data were processed

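Gene expression was measured by RNA sequencing in T47D, SKBR3 and MDA-MB-453 cells, in 27 libraries that form 9 groups of 3. Per the labels, cells were reverse transfected with a pool of siRNAs that targets TLE3 (siTLE3), with 1 that targets FOXA1 (siFOXA1), or with control siRNA (siNS), and total RNA was taken 48 h later with a column kit. The labels number 3 biological replicates per group and do not say whether these were separate cultures on separate days. P-values here measure only the spread between these samples.

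The authors deposited 1 table for each of the 6 comparisons of an siRNA with siNS. Per the submitters' processing notes, STAR 2.5, HTSeq 0.6.1 and DESeq2 were used with the hg19 human genome build, with no further roles, settings or DESeq2 version given. Each deposited table gives read counts per gene as whole numbers. The authors also give FPKM, which the values show to be the count divided by the listed gene length and by the total of the library, on a fixed scale. A further set of deposited columns holds a normalised signal, which the values show to be the count divided by 1 size factor per library. The deposited log2 fold change, p-value and adjusted p-value of each gene come from the authors' own test and were not used for any call here. The deposited gene length was used only for a test of length trends.

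Only the deposited read counts entered the fits. Library totals recovered from the deposited FPKM, for the libraries whose columns match a labelled replicate, showed that at most 0.02054% of a library's counted reads were missing from its table. Each table lists only genes with at least 1 read in either of the first 2 siRNA columns, so genes seen only in siNS are left out of it. At most 14 such genes per table had a mean of 10 or more siNS reads in the other table of the line. The siNS columns of both tables of a line held identical counts, so the 9 libraries of a line could be set side by side.

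Libraries are named by the number their deposited column carries. These are 2, 3 and 4 for T47D siNS, 1, 3 and 4 for T47D siTLE3, 1, 2 and 4 for MDA-MB-453 siNS, and 1 to 3 in the other groups. The labels number every group 1 to 3, so columns of those 3 groups were assigned to their group and not to a labelled replicate.

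Analysis was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. For each comparison the 6 libraries were normalised by TMM, genes were kept by edgeR's filterByExpr, and a quasi-likelihood F test (glmQLFTest) was run, 2-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. Expression is given as CPM, the read count scaled to a common library size with the TMM factors. The siTLE3 and siFOXA1 libraries of a line were compared in the same way. Differences of an siRNA effect between lines were tested with the F test of both line-by-siRNA terms over 18 libraries. Shared calls were set against the number for independent lists and against 20 draws of simulated libraries with no effect. Each draw simulated all 9 libraries of a line, gene by gene, and compared both siRNAs with the same simulated siNS libraries. Deviations that many genes of a real siNS library share are not part of these draws.

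The 25 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a comparison. A list member is counted as risen or fallen when its adjusted p over all genes tested passed, and the count adjusted over the list alone is given beside it.

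Genes named in the text follow a rule. For each comparison with siNS these are the targeted gene and the 6 genes with the largest rise and the 6 with the largest fall among protein-coding genes that passed, had a mean of at least 1 CPM and had no overlap between the 3 siRNA and the 3 siNS libraries. From each list described, up to 4 passing members with the largest change are named. Between the siRNAs and between lines, the 5 genes with the smallest p are named. For genes called in all 3 lines, the 5 per direction with the largest smallest change are named. The receptor genes ESR1, PGR and ERBB2, GATA3, and the TLE and FOXA family are given in every line where tested. Some genes that meet these rules are not reported here, and they remain in the counts and list tests. Where 1 to 3 reads were counted in a group, a CPM ratio from library totals without TMM factors is given, with its 95% counting interval. A group with no reads was set to a floor of 3 counts over the group, also without TMM factors. Intervals and floors cover counting error only.

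The comparisons, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were RLE normalisation, no low-count filter, DESeq2, a fit of the 9 libraries of a line together, a replicate block where the columns allow it, a minimum change of 2-fold, an estimated correlation for the lists, and leaving out each library in turn. Fits without 2 SKBR3 libraries that stand apart, and lists without genes that hold a certain 3' UTR word, were added after the data were seen.

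For the search of 3' UTRs, the longest annotated 3' UTR of each gene was taken from GENCODE release 29 on GRCh38, matched by gene identifier, and no coordinate of that build was used. Each 7-base word was counted as present or absent in UTRs of at least 50 bases. Enrichment was measured against 1000 random gene sets matched on UTR length and base composition, with a family-wise p over all words.

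The procedures were tested on simulated data. With 200 changed genes among negative binomial counts drawn at the fitted spread, the fit recovered 83.6% of genes changed 2-fold for T47D siTLE3 with 15 false calls, 82.1% for T47D siFOXA1 with 12, 46.3% for SKBR3 siTLE3 with 6, 59.7% for SKBR3 siFOXA1 with 3, 83.6% for MDA-MB-453 siTLE3 with 14, and 65.7% for MDA-MB-453 siFOXA1 with 12. The test between lines recovered 78.7% and 75.8% of genes changed 4-fold. A planted rise of the basal list was called in each comparison. Other lists were called as well, 2 for T47D siTLE3, 3 for T47D siFOXA1 and 1 each for MDA-MB-453 siTLE3 and siFOXA1. In SKBR3 siTLE3 and siFOXA1 0 other lists were called. A planted UTR word ranked 1.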

Results

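RNA sequencing measured gene expression in 3 human breast cancer cell lines after silencing of TLE3 or FOXA1. TLE3 encodes a corepressor of the Groucho family, and FOXA1 encodes a pioneer transcription factor of luminal breast epithelium. T47D is an estrogen receptor positive luminal line, and SKBR3 carries an amplified ERBB2 gene. The last line was MDA-MB-453. In each line TLE3 was silenced with an siRNA pool (siTLE3), FOXA1 with another (siFOXA1), and control cells were given a control siRNA (siNS), with RNA taken 48 h later. The 27 libraries form 9 groups of 3 and held 15968223 to 26208135 counted reads each. Libraries are named by the number of their deposited column, which for T47D siNS, T47D siTLE3 and MDA-MB-453 siNS is not the replicate number of the labels.

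Log2 fold changes are siRNA relative to siNS unless stated, from edgeR, with their standard error (SE) in parentheses, and every group had n = 3 libraries. Expression levels are group means of CPM (read counts scaled to a common library size) ± SD. A gene is said to have risen or fallen only where its edgeR adjusted p passed over all genes tested. Gene lists were tested with camera at a preset correlation between genes and again with an estimated correlation. Comparisons, gene lists and the rule for naming genes were fixed before the data were examined, except where a later choice is stated.

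Both targeted genes fell in every line. TLE3 (ENSG00000140332, chr15:70340129-70390515, hg19, minus strand) fell from 136 ± 5.79 to 38.7 ± 2.39 CPM in T47D, from 107 ± 1.90 to 31.6 ± 5.24 CPM in SKBR3 and from 156.5 ± 11.2 to 31.5 ± 0.924 CPM in MDA-MB-453 under siTLE3. The log2 fold changes were -1.81 (0.07), -1.76 (0.17) and -2.31 (0.07), with edgeR adjusted p = 2.42e-10, 0.0031 and 4.92e-10. FOXA1 (ENSG00000129514, chr14:38059189-38069245, hg19, minus strand) fell from 379 ± 7.54 to 83.7 ± 7.07 CPM in T47D, from 369 ± 31.0 to 78.4 ± 2.20 CPM in SKBR3 and from 772 ± 47.2 to 138 ± 7.82 CPM in MDA-MB-453 under siFOXA1. Its log2 fold changes were -2.18 (0.08), -2.24 (0.10) and -2.48 (0.07), with edgeR adjusted p = 2.31e-10, 5.55e-05 and 7.4e-15.

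**Figure D1:**
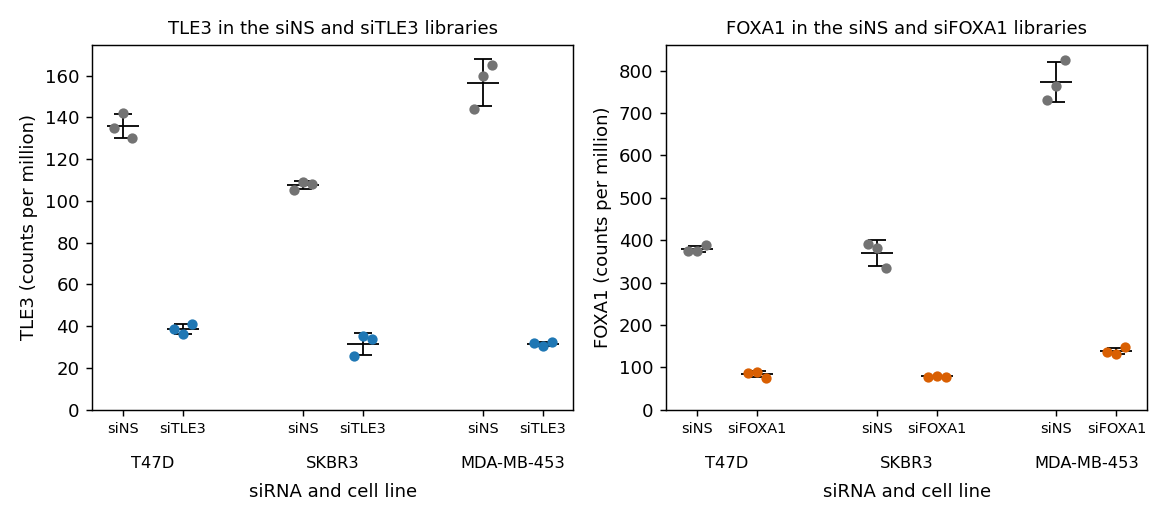
TLE3 and FOXA1 levels in CPM in each library (points), with group mean and SD (bars), by line and siRNA. Each targeted gene is lowest in the libraries given its own siRNA.

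With all libraries, many genes moved in T47D and MDA-MB-453, and fewer in SKBR3 under siTLE3. In T47D, 4007 genes rose and 4211 fell of 15821 tested under siTLE3, and 4038 rose and 4170 fell of 15553 under siFOXA1. SKBR3 had 528 risen and 286 fallen of 14382 under siTLE3, and 1490 risen and 1256 fallen of 14361 under siFOXA1. MDA-MB-453 had 2285 risen and 2381 fallen of 14575 under siTLE3, and 3413 risen and 3459 fallen of 14586 under siFOXA1. Changes of at least 2-fold numbered 1299 up and 462 down, 1195 up and 878 down, 306 up and 164 down, 577 up and 401 down, 262 up and 257 down, and 863 up and 629 down in the same order. The SKBR3 siTLE3 count of 814 fell to 107 without siTLE3 2 and rose to 4161 without siTLE3 1 and siNS 3. Its size thus depends on the libraries used, as detailed with that comparison. Even the count of 4161 was below the 6675 of SKBR3 siFOXA1 without siNS 3 and the 4666 of MDA-MB-453 siTLE3. The biological coefficient of variation was 0.209 and 0.165 in the SKBR3 fits and 0.08 to 0.0867 in the others.

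**Figure D2:**
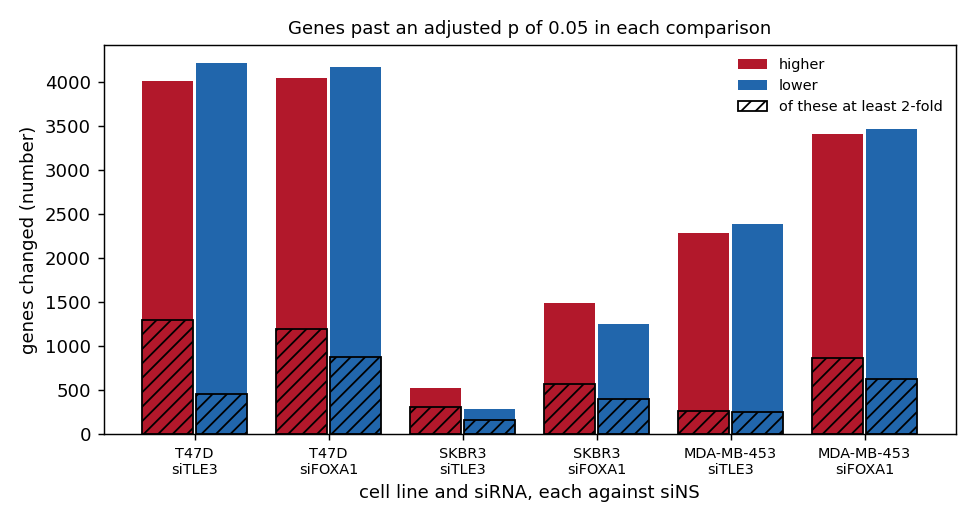
Number of genes with higher (red) and lower (blue) expression than siNS by edgeR for each line and siRNA, with changes of at least 2-fold hatched. With all libraries SKBR3 under siTLE3 has the fewest, a count that depends on single libraries.

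Silencing of TLE3 in T47D asked which genes the corepressor holds down in an estrogen receptor positive line. Some genes of multiciliated cells rose from low levels, with the set as a whole left open in the closing section. The estrogen and progesterone receptor genes rose, and some inflammatory cytokine genes rose. CDC20B, which hosts a microRNA locus of multiciliated cells, rose by 8.44 (0.26) to 31.3 ± 2.22 CPM. FOXJ1, the regulator of motile cilia, rose by 6.54 (0.14) from 0.603 ± 0.155 to 57.0 ± 3.55 CPM. FOXN4, a forkhead factor of multiciliated progenitors, rose by 5.29 (0.56), and RP1, an axonemal microtubule gene, rose by 5.14 (0.61). The myelin gene PMP22 rose by 5.29 (0.27) and the mucosal keratin gene KRT4 by 5.66 (0.23), although reads shared with other keratin genes leave the level of KRT4 uncertain. The estrogen-induced early gene EGR3 fell by 2.90 (0.17), the protocadherin PCDH18 by 2.88 (0.27), the splicing regulator CELF3 by 2.87 (0.43), the cortexin CTXN1 by 2.79 (0.11), JAKMIP2 by 2.68 (0.56) and the Rap GTPase-activating gene SIPA1 by 2.60 (0.07). Among these 12 genes the edgeR adjusted p reached at most 0.00111.

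PGR rose by 1.81 (0.09) from 196 ± 12.1 to 688 ± 90.1 CPM, and ESR1 rose by 0.96 (0.07) from 133 ± 7.58 to 258 ± 15.9 CPM in T47D under siTLE3. Of 39 luminal genes, 19 rose, 10 fell and 10 did not pass, or 20 up and 11 down adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.023 preset, adjusted p = 0.55 with an estimated correlation). The secreted AGR3 rose by 1.63 (0.11), the carbonic anhydrase CA12 by 1.61 (0.07) and the transcription factor MYB by 1.43 (0.09). Of 48 estrogen response genes 19 rose, 15 fell and 14 did not pass, and the list did not pass (camera adjusted p = 0.43). The longest 3' UTR of CA12 holds AGCCTTA, a 7-base word that is frequent among genes raised by both siRNAs in all lines and is weighed in the closing section.

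Some inflammatory genes rose in T47D under siTLE3 from low levels. Tested genes low in siNS tended to rise here, as random lists matched on the siNS levels of multiciliated genes had a median of 0.22. Genes nearly absent in siNS were listed and kept by the filter only if they had siTLE3 reads. This selection by itself favours a rise among them. Whether the tendency or the selection covers the inflammatory genes was not tested. The cytokine genes IL32, CCL20, LIF and CXCL1 rose by 3.02 (0.39), 2.17 (0.57), 2.09 (0.30) and 2.05 (0.42), with none above 3.2 CPM. Of 21 NF-kB genes 17 rose, 1 fell and 3 did not pass, the same counts as adjusted over the list alone, with median 0.84 (camera adjusted p = 0.0096 preset, adjusted p = 0.55 with an estimated correlation). Of 28 basal genes 14 rose, 2 fell and 12 did not pass, the same as adjusted over the list alone, with median 0.37 (camera adjusted p = 0.017 preset, adjusted p = 0.55 with an estimated correlation). The annexin ANXA1 rose by 3.22 (0.17), the kallikrein KLK5 by 2.07 (0.53), and the keratin genes KRT16 and KRT15, uncertain among their paralogs, by 1.51 (0.43) and 1.49 (0.09).

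Further T47D genes moved under siTLE3 in lists that did not pass. Wnt genes TCF7, NKD2, WNT5A and AXIN2 rose by 2.79 (0.28), 2.52 (0.25), 2.47 (0.40) and 2.37 (0.49), while 7 of 19 Wnt genes rose, 7 fell and 5 did not pass. The Wnt list had a median of 0.00, a mean of 0.36 and a camera test pointing down (adjusted p = 0.91). Cholesterol synthesis genes SQLE and IDI1 fell by 0.79 (0.06) and 0.71 (0.07), and the elongase ELOVL6 by 1.28 (0.12). Of 26 cholesterol and fatty acid genes 3 rose, 15 fell and 8 did not pass (camera adjusted p = 0.064). Without siNS 3 this list passed (camera adjusted p = 0.048), as did the interferon list (camera adjusted p = 0.013), which raised the lists called from 3 to 5. The Notch ligand DLL1 rose by 2.35 (0.17), the peptide hormone ADM by 2.60 (0.09) and the cell cycle kinase CDK2 by 2.54 (0.13). The amino acid transporter SLC7A5 fell by 1.38 (0.07).

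Silencing of FOXA1 in T47D asked which genes depend on the pioneer factor there. The basal list rose at either correlation. The mesenchymal list rose and the interferon, proliferation and luminal lists fell at the preset correlation only (camera adjusted p = 0.39, 0.67, 0.39 and 0.23 with an estimated correlation). The transcription factor SNAI2 rose by 5.38 (0.50), the alkaline phosphatase ALPL by 5.36 (0.27), the cystatin CST7 by 5.26 (0.21), the orphan receptor GPR20 by 5.39 (0.44), KLK5 by 5.19 (0.33) and the calcium-binding CABP7 by 4.95 (0.52). The chemokine receptor CXCR4 fell by 3.92 (0.17) from 16.5 ± 0.965 to 1.08 ± 0.228 CPM. The cadherin CDH13 fell by 4.0 (0.24), the apolipoprotein APOL3 by 4.05 (0.44), TM4SF18 by 4.30 (0.21), the steroid receptor associated C1orf64 by 4.44 (0.40) and the androgen glucuronidation gene UGT2B15 by 4.63 (0.54). UGT2B15 has near-identical family members, so its level is uncertain. For these 12 genes the edgeR adjusted p was at most 9.1e-06.

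Of 30 basal genes 21 rose, 4 fell and 5 did not pass, the same as adjusted over the list alone, with median 1.06 in T47D under siFOXA1 (camera adjusted p = 2.8e-12 preset, adjusted p = 0.028 with an estimated correlation). ANXA1 rose by 4.85 (0.14) from 1.83 ± 0.373 to 53.3 ± 6.09 CPM, and KRT16 and KRT14, uncertain among keratin paralogs, by 4.43 (0.22) and 3.98 (0.45). The matrix gene SPARC rose by 3.53 (0.22), the repressor ZEB1 by 2.81 (0.59) and the tenascin TNC by 2.29 (0.20). Of 22 mesenchymal genes 11 rose, 2 fell and 9 did not pass, with median 0.43 (camera adjusted p = 0.034 preset, adjusted p = 0.39 with an estimated correlation). That list did not pass without siFOXA1 3 (camera adjusted p = 0.061). The neural adhesion gene L1CAM rose by 2.73 (0.08), within 31 adhesion genes of which 17 rose, 9 fell and 5 did not pass (median 0.27, camera adjusted p = 0.00022 preset, adjusted p = 0.24 with an estimated correlation).

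The trefoil peptide TFF1 fell by 3.57 (0.14), the disulfide isomerase AGR2 by 2.16 (0.10) and the Ets factor SPDEF by 1.92 (0.07) in T47D under siFOXA1. Of 39 luminal genes 14 rose, 19 fell and 6 did not pass, with median -0.17 (camera adjusted p = 0.013 preset, adjusted p = 0.23 with an estimated correlation). The fallen members include FOXA1 itself, the targeted gene, so part of this fall was set by the design. PGR, also a luminal list member, rose by 1.28 (0.10). Of 26 cholesterol and fatty acid genes 4 rose, 14 fell and 8 did not pass, or 4 up and 16 down adjusted over the list alone (median -0.27, camera adjusted p = 0.032 preset, adjusted p = 0.24 with an estimated correlation). SQLE and FASN fell by 0.77 (0.07) and 0.77 (0.09). The adipogenic factor PPARG had 1 to 3 reads over the siNS group and rose with a CPM ratio of 39.6 (counting interval 6.74 to 1600).

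Of 45 interferon genes none rose, 42 fell and 3 did not pass, with median -1.61 in T47D under siFOXA1 (camera adjusted p = 9.2e-10 preset, adjusted p = 0.67 with an estimated correlation). The antiviral gene OAS2 fell by 2.84 (0.33) from 830 ± 329 to 116 ± 59.1 CPM, and CMPK2, IFI44L and MX2 fell by 3.18 (0.38), 2.95 (0.39) and 2.88 (0.33). Of 44 proliferation genes 1 rose, 38 fell and 5 did not pass, with median -0.74 (camera adjusted p = 2.3e-13 preset, adjusted p = 0.39 with an estimated correlation). The replication clamp PCNA fell by 1.52 (0.09), and the cell cycle factors E2F2 and E2F8 by 1.52 (0.11) and 1.48 (0.15), while CDK2 rose by 1.56 (0.15). Of 22 cell cycle inhibitor and p53 genes 14 rose, 4 fell and 4 did not pass, or 15 up and 4 down adjusted over the list alone, with median 0.42 (camera adjusted p = 0.0046 preset, adjusted p = 0.2 with an estimated correlation). CDKN1A, the p21 gene, rose by 1.29 (0.07), the death receptor TNFRSF10B by 1.32 (0.07) and the kinase PLK3 by 2.08 (0.34), the latter pair with AGCCTTA in their longest 3' UTR. Of 52 ribosomal protein genes 35 rose, 1 fell and 16 did not pass, or 36 up and 1 down adjusted over the list alone (median 0.30, camera adjusted p = 0.004 preset, adjusted p = 0.71 with an estimated correlation), with RPLP2 up by 0.81 (0.09).

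A direct comparison in T47D asked which genes separate the siRNAs. Relative to siFOXA1, siTLE3 libraries had more FOXJ1 by 8.22 (0.21), CDC20B by 8.31 (0.23) and TFF1 by 4.70 (0.12). AL050303.1 (ENSG00000269011, chr21:15051621-15053459, hg19, minus strand) was higher by 7.52 (0.19), at 32.4 ± 1.06 against 0.171 ± 0.0728 CPM. The largest edgeR adjusted p of these 4 was 5.95e-10. Of 16053 genes 3617 were higher and 3502 lower under siTLE3. Both siRNAs moved 4431 genes the same way against siNS, 2137 up and 2294 down, and 841 in opposite ways, with r = 0.495 over all genes. Independent call lists would share 969.7 raised and 1149 lowered genes. Libraries were also simulated without any effect, siNS included, with the simulated siNS libraries shared by both comparisons. These gave a mean r of 0.52, a covariance of 0.02 against 0.233 observed, and at most 1 shared call. Libraries without effect have few calls to share, so this low number was set by their design. It cannot weigh what the shared siNS libraries add to the observed shared calls.

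Silencing of TLE3 in SKBR3 asked the same of an ERBB2-amplified line. The growth factor PDGFA rose by 3.24 (0.42), the Hedgehog effector GLI3 by 2.99 (0.28), the ubiquitin ligase RNF144A by 2.90 (0.29) and the matrix ligand NPNT by 2.72 (0.21) from 6.05 ± 1.35 to 39.8 ± 4.81 CPM. The decarboxylase DDC fell by 3.59 (0.30) from 13.2 ± 2.93 to 1.09 ± 0.390 CPM, the secreted CRISP3 by 2.73 (0.22) and the chloride transporter CLCN4 by 2.13 (0.32). The largest edgeR adjusted p of these 7 was 0.00982, and each call held when any 1 library was left out. The lactate transporter SLC16A1 rose by 2.77 (0.39), FAM105A rose by 2.71 (0.38), PKD1L1 fell by 2.35 (0.34) and C21orf119 fell by 2.26 (0.31), but without siTLE3 2 their edgeR adjusted p was 0.051, 0.0531, 0.0588 and 0.0504. The longest 3' UTRs of PDGFA, RNF144A and SLC16A1 hold AGCCTTA.

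The number of called genes in SKBR3 under siTLE3 depended on the fit and on 5 of the 6 libraries. Against 814 genes with all libraries, 464 were called without siTLE3 1, 107 without siTLE3 2, 362 without siTLE3 3, 302 without siNS 1, 269 without siNS 2 and 762 without siNS 3. It was 1502 with DESeq2 and 1962 in a fit of 9 libraries. Without both siTLE3 1 and siNS 3, which stand apart from their groups, it was 4161, in a fit added after the data were seen. The kinase gene CDK2 rose by 1.98 (0.20), the transcription factor SOX9 by 1.85 (0.17), TGFB2 by 2.17 (0.20), the matrix gene TGFBI by 1.94 (0.16), the laminin LAMC1 by 1.44 (0.17) and the corepressor subunit TBL1X by 1.49 (0.15). The antiviral gene PARP12 rose by 1.72 (0.22) and the elongation factor ELL2 by 1.43 (0.17), while the aminotransferase ABAT and the serine synthesis gene PHGDH fell by 1.43 (0.17) and 1.42 (0.22). Each of these 10 calls held with any library left out (largest edgeR adjusted p = 0.0105 with all libraries). Over all 74 called genes that the naming rule covers in this comparison, 22 kept the call with any library left out and 52 did not. SOX9 and ELL2 hold AGCCTTA in their longest 3' UTR.

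Gene lists moved in SKBR3 under siTLE3 at the preset correlation only. Of 30 basal genes 7 rose, none fell and 23 did not pass, or 10 up adjusted over the list alone (median 0.49, camera adjusted p = 6.2e-06 preset, adjusted p = 0.12 with an estimated correlation). Of 17 mesenchymal genes 4 rose and 13 did not pass, or 7 up and 1 down over the list alone (median 0.42, camera adjusted p = 0.00023 preset, adjusted p = 0.25 with an estimated correlation). Of 44 proliferation genes 10 rose and 34 did not pass, or 24 up and 1 down over the list alone (median 0.49, camera adjusted p = 8.8e-10 preset, adjusted p = 0.25 with an estimated correlation). Of 28 adhesion genes 6 rose, 1 fell and 21 did not pass, or 8 up and 1 down over the list alone (median 0.18, camera adjusted p = 0.0013 preset, adjusted p = 0.25 with an estimated correlation). ANXA1 rose by 1.82 (0.27), but its edgeR adjusted p was 0.0641 without siTLE3 2. The topoisomerase TOP2A rose by 1.21 (0.21), but its edgeR adjusted p was 0.0508 without siNS 2, 0.0599 without siTLE3 1 and 0.0839 without siTLE3 2.

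Of 19 NF-kB genes in SKBR3 under siTLE3 1 rose and 18 did not pass, or 4 up over the list alone (median 0.47, camera adjusted p = 0.0087 preset, adjusted p = 0.25 with an estimated correlation), and the list did not pass without siNS 1 (camera adjusted p = 0.056). Of 25 cholesterol and fatty acid genes 2 fell and 23 did not pass, or 1 up and 6 down over the list alone (median -0.27, camera adjusted p = 0.021 preset, adjusted p = 0.25 with an estimated correlation). The camera adjusted p of that list was 0.059 without siTLE3 2, 0.061 without siTLE3 3, 0.056 without siNS 1 and 0.097 without siNS 2. Of 13 genes of the 17q12 amplicon 1 fell and 12 did not pass, or 2 down over the list alone (median -0.32, camera adjusted p = 0.026 preset, adjusted p = 0.49 with an estimated correlation), and the list did not pass without siTLE3 1 (camera adjusted p = 0.078). Of 52 ribosomal protein genes none passed with edgeR or DESeq2, and 3 were lower at an unadjusted edgeR p under 0.05, yet the list passed (median -0.38, camera adjusted p = 7.5e-05 preset, adjusted p = 0.73 with an estimated correlation). Without siNS 3 it did not pass (camera adjusted p = 0.19), and ribosomal protein genes took 10.1% of the reads of siNS 3 against 6.7% and 6.88% in the other siNS libraries.

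Silencing of FOXA1 in SKBR3 raised the basal and proliferation lists at either correlation. It lowered the androgen response, luminal and lipid lists at the preset correlation only (camera adjusted p = 0.062, 0.062 and 0.061 with an estimated correlation). The keratin genes KRT5 and KRT9, uncertain among their paralogs, rose by 5.53 (0.68) and 4.57 (0.32). The channel adaptor STAC2 rose by 5.42 (0.16) from 5.69 ± 1.02 to 244 ± 13.3 CPM, PDGFA by 4.28 (0.32), the water channel AQP1 by 3.91 (0.24) and SLC16A1 by 3.82 (0.30). The transporter ABCC11 fell by 4.0 (0.13) from 120 ± 11.9 to 7.46 ± 0.5 CPM, the prostatic acid phosphatase ACPP by 3.79 (0.40), the lipid flippase ATP8B2 by 3.77 (0.21) and MS4A7 by 4.08 (0.46). PKD1L1 and ABCC12 had 1 to 3 reads over the siFOXA1 group and fell with CPM ratios of 0.0132 (counting interval 0.00159 to 0.0487) and 0.0145 (0.00296 to 0.0429). All 12 genes had an edgeR adjusted p of at most 0.00138. The number of called genes was 2746, against 1280, 1292 and 1266 without siFOXA1 1, 2 and 3, and 6675 without siNS 3.

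Of 31 basal genes 17 rose, 1 fell and 13 did not pass in SKBR3 under siFOXA1, or 23 up and 2 down over the list alone (median 0.91, camera adjusted p = 1.8e-12 preset, adjusted p = 0.014 with an estimated correlation). ANXA1 rose by 3.69 (0.17). Of 44 proliferation genes 39 rose, none fell and 5 did not pass, or 40 up over the list alone (median 0.94, camera adjusted p = 5.5e-31 preset, adjusted p = 0.014 with an estimated correlation). TOP2A rose by 1.69 (0.18) from 210 ± 52.8 to 677 ± 35.8 CPM, the mitotic kinase PLK1 by 1.46 (0.11), the checkpoint kinase BUB1B by 1.49 (0.17) and CDK2 by 1.85 (0.18). MYC rose by 0.90 (0.10), the receptor NOTCH1 by 1.30 (0.15) and its ligand JAG1 by 1.42 (0.24), the latter pair with AGCCTTA in their longest 3' UTR. Of 17 Notch genes 4 rose, 2 fell and 11 did not pass, and the list did not pass (camera adjusted p = 0.11). Of 17 mesenchymal genes 5 rose, 2 fell and 10 did not pass, or 9 up and 3 down over the list alone (median 0.56, camera adjusted p = 0.013 preset, adjusted p = 0.36 with an estimated correlation), and the list did not pass without siNS 1 (camera adjusted p = 0.071). LOXL2, a collagen crosslinking gene, rose by 1.52 (0.12) and the thrombospondin THBS1 by 1.47 (0.17).

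Of 35 luminal genes 4 rose, 12 fell and 19 did not pass in SKBR3 under siFOXA1, or 4 up and 14 down over the list alone (median -0.23, camera adjusted p = 0.00018 preset, adjusted p = 0.062 with an estimated correlation). As in T47D, the targeted gene FOXA1 is among the fallen members of this list. AGR2 fell by 1.91 (0.14) and TFF3 by 2.02 (0.28). Of 41 estrogen response genes 3 rose, 11 fell and 27 did not pass, or 5 up and 13 down over the list alone (median -0.17, camera adjusted p = 0.016 preset, adjusted p = 0.11 with an estimated correlation). ABAT fell by 2.40 (0.19) and the stress factor XBP1 by 1.52 (0.10). Of 29 androgen response genes 2 rose, 12 fell and 15 did not pass, or 6 up and 14 down over the list alone. That list had a median of 0.13 but a mean of -0.55 and a test pointing down (camera adjusted p = 3e-04 preset, adjusted p = 0.062 with an estimated correlation). The lipocalin APOD fell by 1.79 (0.14).

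Of 25 cholesterol and fatty acid genes none rose, 11 fell and 14 did not pass in SKBR3 under siFOXA1, or 14 down over the list alone (median -0.40, camera adjusted p = 2.9e-06 preset, adjusted p = 0.061 with an estimated correlation). MVD and MVK of sterol synthesis fell by 1.31 (0.19) and 1.01 (0.16). Of 23 hypoxia and glycolysis genes none rose, 7 fell and 16 did not pass, or 8 down over the list alone (median -0.20, camera adjusted p = 0.001 preset, adjusted p = 0.067 with an estimated correlation), with the hypoxia gene NDRG1 down by 1.64 (0.10). None of 52 ribosomal protein genes passed with edgeR, where 17 were lower at an unadjusted p under 0.05, and 7 were lower with DESeq2, while the list had median -0.38 (camera adjusted p = 3e-04 preset, adjusted p = 0.78 with an estimated correlation). Without siNS 3, whose share of ribosomal protein reads was high, the list still passed (camera adjusted p = 0.0059).

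Between the siRNAs in SKBR3, siTLE3 libraries had more ABCC11 by 3.78 (0.12) and FOXA1 by 2.66 (0.10). They had less KRT9 by a log2 fold change of -4.90 (0.17), STAC2 by -5.59 (0.22) and the kinase gene SGK2 by -4.02 (0.17), with a largest edgeR adjusted p of 3.34e-06 for these 5. Of 14195 genes 1525 were higher and 1311 lower under siTLE3, 2836 in all. Without a library the number was 5732 (siTLE3 1), 1757 (siTLE3 2), and 1349, 1393 and 1336 (siFOXA1 1, 2 and 3). Both siRNAs moved 471 genes the same way, 340 up and 131 down, and 42 in opposite ways, with r = 0.504. Independent lists would share 53.31 raised and 25.46 lowered. Simulated libraries without effect gave a mean r of 0.505, a covariance of 0.046 against 0.164 observed, and no shared call, the last set by their design as in T47D. The 513 shared calls became 320 without siTLE3 1, 87 without siTLE3 2, 263 without siTLE3 3, 207 without siNS 1 and 189 without siNS 2. They numbered 865 with DESeq2 and 2901 without both siTLE3 1 and siNS 3, a fit added after the data were seen.

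Silencing of TLE3 in MDA-MB-453 raised the proliferation list and lowered the interferon and antigen presentation lists at the preset correlation only (camera adjusted p = 0.9 for each with an estimated correlation). The scavenger receptor gene DMBT1 rose by 2.45 (0.12) from 43.6 ± 9.24 to 237 ± 25.2 CPM. The xenobiotic gene CYP1A2 rose by 2.89 (0.45), the peroxisomal oxidase ACOX2 by 2.81 (0.40), the transporter ABCC12 by 2.53 (0.19), the interleukin antagonist IL1RN by 2.49 (0.40) and BCAS1 by 2.42 (0.20). APOL3 fell by 3.30 (0.32) from 41.6 ± 13.8 to 4.05 ± 2.56 CPM, the endocytic receptor LRP2 by 3.21 (0.39) and the complement-like C1QL1 by 3.33 (0.51). The retinoid-induced RARRES3 fell by 2.94 (0.37), IQSEC3 by 2.90 (0.55) and the carnitine gene BBOX1 by 2.73 (0.44). The largest edgeR adjusted p of these 12 genes was 0.00105. The longest 3' UTR of RARRES3 holds GAGTACT, a word frequent among genes that siTLE3 alone lowered, which the closing section weighs.

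Of 43 interferon genes 1 rose, 21 fell and 21 did not pass in MDA-MB-453 under siTLE3, the same as over the list alone (median -0.48, camera adjusted p = 1.7e-05 preset, adjusted p = 0.9 with an estimated correlation). OASL fell by 2.19 (0.31) from 396.5 ± 158 to 86.3 ± 37.8 CPM, HERC5 by 1.92 (0.27) and IFIT2 by 1.91 (0.34). Of 18 antigen presentation genes 2 rose, 11 fell and 5 did not pass, or 12 down over the list alone (median -0.53, camera adjusted p = 0.014 preset, adjusted p = 0.9 with an estimated correlation). B2M fell by 1.04 (0.20) and HLA-B, uncertain among near-identical HLA genes, by 1.44 (0.32). The chemokine genes IL8 and CCL5 fell by 2.68 (0.31) and 2.31 (0.44). Of 15 NF-kB genes 1 rose, 5 fell and 9 did not pass, and that list did not pass (camera adjusted p = 0.22). Of 44 proliferation genes 33 rose, none fell and 11 did not pass, or 36 up over the list alone (median 0.47, camera adjusted p = 7.4e-11 preset, adjusted p = 0.9 with an estimated correlation). CDK2 rose by 1.57 (0.13), the cyclin CCNE1 by 1.40 (0.19) and BUB1B by 0.92 (0.12).

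Of 35 luminal genes 17 rose, 6 fell and 12 did not pass in MDA-MB-453 under siTLE3, or 17 up and 7 down over the list alone (median 0.14, camera adjusted p = 0.014 preset, adjusted p = 0.7 with an estimated correlation). TFF1 rose by 2.41 (0.18) and AGR2 by 1.28 (0.07) from 479 ± 27.1 to 1163 ± 39.2 CPM, while the prolactin receptor PRLR fell by 1.02 (0.07). Of 20 basal genes 7 rose, 2 fell and 11 did not pass, or 8 up over the list alone (median 0.36, camera adjusted p = 0.047 preset, adjusted p = 0.7 with an estimated correlation). The camera adjusted p of the basal list was 0.078 without siTLE3 1, 0.098 without siTLE3 2, 0.065 without siNS 1 and 0.14 without siNS 2. ANXA1 rose by 1.99 (0.44) and the protease inhibitor SLPI by 1.43 (0.14). Of 30 receptor kinase and MAPK genes 8 rose, 5 fell and 17 did not pass, or 9 up and 6 down over the list alone (median 0.15, camera adjusted p = 0.045 preset, adjusted p = 0.7 with an estimated correlation). That list did not pass without siTLE3 2 (camera adjusted p = 0.074) or without siNS 1 (camera adjusted p = 0.065). In a test added after the data were seen, neither the basal nor the receptor kinase list passed without genes that hold AGCCTTA (camera adjusted p = 0.096 and 0.29). The early response gene EGR1 rose by 2.30 (0.10), with AGCCTTA in its longest 3' UTR. The Notch feedback gene NRARP fell by 1.25 (0.08), and the stress cytokine GDF15 and CDKN1A rose by 1.57 (0.18) and 1.42 (0.15).

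Silencing of FOXA1 in MDA-MB-453 raised the basal list at either correlation and, from near absence, some epidermal genes. The proliferation list fell at the preset correlation only (camera adjusted p = 0.85 with an estimated correlation). The iron-binding secretory gene LTF rose by 9.18 (0.23) to 59.0 ± 2.31 CPM. The epidermal protease CASP14 rose with a CPM ratio of 542 (counting interval 185 to 2630) and KRT5 with a ratio of 180 (31.9 to 7160), each from 1 to 3 siNS reads. The cornified envelope gene IVL and the microvillar myosin MYO7B had no siNS reads and rose at least 56.6-fold and 62.9-fold. KRT16 rose by 7.87 (0.28), and KRT5 and KRT16 are uncertain among keratin paralogs. The glutamate transporter SLC1A7 fell by 4.25 (0.13) from 940 ± 77.3 to 49.3 ± 11.4 CPM. CREB3L1, a membrane-bound stress factor, fell by 4.31 (0.10), AFF3 by 4.30 (0.23), CDH13 by 4.73 (0.43), MS4A7 by 4.53 (0.61) and the testis antigen MAGEC1 by 4.22 (0.42). Across these 12 genes edgeR adjusted p was at most 5.88e-06.

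Of 22 basal genes 19 rose, 1 fell and 2 did not pass in MDA-MB-453 under siFOXA1, the same as over the list alone (median 2.64, camera adjusted p = 5.9e-34 preset, adjusted p = 0.0073 with an estimated correlation). ANXA1 rose by 6.81 (0.19) from 0.354 ± 0.183 to 41.8 ± 2.30 CPM. Of 23 adhesion genes 15 rose, 4 fell and 4 did not pass, or 16 up over the list alone (median 0.65, camera adjusted p = 2.9e-10 preset, adjusted p = 0.19 with an estimated correlation). The P-cadherin gene CDH3 rose by 2.45 (0.12), the laminins LAMC1 and LAMB1 by 2.13 (0.09) and 2.02 (0.11), and the desmoglein DSG2 by 2.63 (0.08), with AGCCTTA in the longest 3' UTR of DSG2. Of 14 mesenchymal genes 6 rose and 8 did not pass (median 0.65, camera adjusted p = 0.024 preset, adjusted p = 0.26 with an estimated correlation), with the cadherin CDH2 up by 3.06 (0.09). Of 29 receptor kinase and MAPK genes 8 rose, 14 fell and 7 did not pass, or 9 up and 15 down over the list alone (median -0.22, camera adjusted p = 0.026 preset, adjusted p = 0.26 with an estimated correlation). EGFR rose by 2.43 (0.19), while the Ets factor ETV5 fell by 2.15 (0.21) and IGFBP3 by 2.69 (0.14).

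Of 44 proliferation genes 1 rose, 28 fell and 15 did not pass in MDA-MB-453 under siFOXA1 (median -0.34, camera adjusted p = 0.0032 preset, adjusted p = 0.85 with an estimated correlation). The phosphatase CDC25A fell by 1.10 (0.09), while the cell cycle inhibitors CDKN1C and CDKN2B rose by 4.45 (0.37) and 2.69 (0.14). Of 38 luminal genes 18 rose, 14 fell, FOXA1 itself included, and 6 did not pass, with median 0.30, and the list did not pass (camera adjusted p = 0.36). Of 15 Notch genes 7 rose and 8 fell, and that list did not pass either (camera adjusted p = 0.72). AGR2 fell by 2.69 (0.08), the androgen-induced PIP by 2.69 (0.15), XBP1 by 1.42 (0.07), the Notch glycosyltransferase LFNG by 2.35 (0.10) and GDF15 by 3.78 (0.21). Of 5 stromal genes 2 fell and 3 did not pass (median -1.57, camera adjusted p = 0.031 preset, adjusted p = 0.43 with an estimated correlation), and the list did not pass without siFOXA1 1 (camera adjusted p = 0.092) or siFOXA1 3 (camera adjusted p = 0.053). The collagen COL1A1 fell by 1.57 (0.07). Of 52 ribosomal protein genes 42 rose, 1 fell and 9 did not pass (median 0.28, camera adjusted p = 0.00043 preset, adjusted p = 0.84 with an estimated correlation).

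Between the siRNAs in MDA-MB-453, siTLE3 libraries had more GDF15 by 5.36 (0.08), AGR2 by 3.99 (0.07) and the sialyltransferase ST3GAL1 by 3.45 (0.06). They had less of the glycerol channel AQP3, with a log2 fold change of -3.93 (0.06), and of the arginine synthesis gene ASS1, with -4.79 (0.07). At most, the edgeR adjusted p of these 5 was 1.26e-21. Of 14484 genes 3905 were higher and 3783 lower under siTLE3. Both siRNAs moved 2317 genes the same way, 1160 up and 1157 down, and 724 in opposite ways, with r = 0.353. Independent lists would share 520.5 raised and 578.2 lowered. Simulated libraries without effect gave a mean r of 0.511, a covariance of 0.023 against 0.113 observed, and at most 3 shared calls, a low number again set by their design.

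Receptor genes were set side by side across lines. ERBB2 rose under siFOXA1 by 0.65 (0.07) in T47D and 0.43 (0.06) in MDA-MB-453, with AGCCTTA in its 3' UTR. In SKBR3 ERBB2 fell by 0.31 (0.08) under siFOXA1, a call lost without siFOXA1 1, 2 or 3 or siNS 1 or 2 (edgeR adjusted p = 0.113, 0.114, 0.12, 0.066 and 0.0819), with log2 fold changes of -0.326 to -0.295 in those fits. Under siTLE3 in T47D ERBB2 rose by 0.19 (0.06), lost without siTLE3 3, siNS 2 or siNS 4 (edgeR adjusted p = 0.0518, 0.0868 and 0.07). ESR1 rose by 0.24 (0.09) in T47D under siFOXA1, lost without siFOXA1 1 or 2 or siNS 2, 3 or 4 (edgeR adjusted p = 0.126, 0.12, 0.0614, 0.0887 and 0.166). Under siTLE3 ERBB2 did not pass in SKBR3 or MDA-MB-453, at -0.19 (0.14) and 0.15 (0.06). ESR1 did not pass in SKBR3 under siTLE3 or siFOXA1, at -0.02 (0.42) and 0.53 (0.44), or in MDA-MB-453 under siFOXA1, at 0.88 (0.61), and PGR rose by 2.88 (0.65) in MDA-MB-453 under siFOXA1 from 0.0982 ± 0.0572 CPM.

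GATA3, a luminal transcription factor, rose under siTLE3 in T47D and MDA-MB-453 by 0.43 (0.06) and 0.43 (0.07), and under siFOXA1 rose by 0.24 (0.07) in T47D and fell by 0.93 (0.07) in MDA-MB-453. In SKBR3 GATA3 did not pass under siTLE3 or siFOXA1, at 0.33 (0.14) and -0.23 (0.09). FOXA1 rose by 0.54 (0.07) in T47D under siTLE3 and did not pass in SKBR3 or MDA-MB-453, at 0.41 (0.14) and 0.03 (0.07). TLE3 fell by 0.79 (0.07) in MDA-MB-453 under siFOXA1, and rose by 0.22 (0.07) in T47D, the latter lost without siFOXA1 2, siNS 2 or siNS 4 (edgeR adjusted p = 0.0805, 0.0692 and 0.0967). TLE1, a paralog, rose under siTLE3 by 0.67 (0.06) in T47D and 0.60 (0.06) in MDA-MB-453, and fell by 0.74 (0.07) in T47D under siFOXA1. The paralog TLE4 rose by 1.17 (0.07) in MDA-MB-453 under siTLE3 and by 0.29 (0.08) under siFOXA1. TLE4 rose by 1.95 (0.40) in SKBR3 under siFOXA1, lost without siFOXA1 1 (edgeR adjusted p = 0.0615). The short family member AES fell under siTLE3 by 0.96 (0.07) in T47D and 0.75 (0.07) in MDA-MB-453, and by 0.58 (0.07) in T47D under siFOXA1. TLE6 fell by 1.08 (0.18) and 2.23 (0.20) in T47D under siTLE3 and siFOXA1, and by 1.18 (0.21) in MDA-MB-453 under siFOXA1. TLE2 rose by 0.60 (0.10) in T47D under siTLE3 and fell by 0.49 (0.12) in MDA-MB-453 under siFOXA1. In SKBR3 under siTLE3 no paralog passed over all genes, with TLE1 at 0.49 (0.14), TLE2 at -0.23 (0.24), TLE4 at 1.64 (0.41), TLE6 at -1.01 (0.34) and AES at -0.81 (0.22), while over the list alone 3 of 7 family members rose and 3 fell, TLE3 included. In MDA-MB-453 under siTLE3, TLE2 and TLE6 did not pass, at 0.05 (0.10) and 0.06 (0.19). Under siFOXA1 there was no call for TLE2 in T47D, at 0.27 (0.12), for TLE1 and AES in MDA-MB-453, at -0.05 (0.06) and -0.10 (0.07), or in SKBR3 for TLE1 at 0.23 (0.10), TLE2 at 0.07 (0.17), TLE3 at 0.08 (0.09), TLE6 at -0.19 (0.24) and AES at -0.24 (0.15). The family list passed under siFOXA1 in T47D, with 1 risen, 4 fallen and 1 not passed of 6 (camera adjusted p = 0.001 preset, adjusted p = 0.2 with an estimated correlation), and in MDA-MB-453, with 1 risen, 4 fallen and 2 not passed of 7 (camera adjusted p = 0.0013 preset, adjusted p = 0.28 with an estimated correlation), both with FOXA1 itself as a member.

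**Figure D3:**
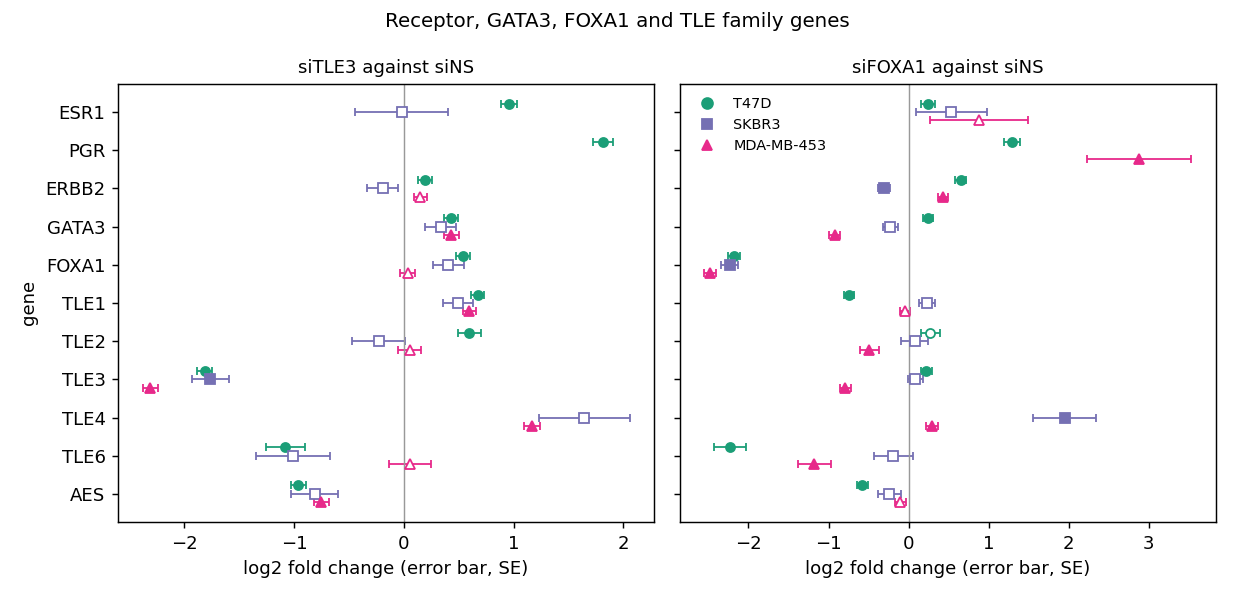
Log2 fold change and SE of receptor, GATA3, TLE and FOXA genes against siNS in T47D (circles), SKBR3 (squares) and MDA-MB-453 (triangles). Filled symbols passed over all genes by edgeR, and open symbols did not.

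Set directly against siFOXA1, siTLE3 left GATA3 higher in MDA-MB-453 and SKBR3, by log2 fold changes of 1.37 (0.05) and 0.58 (0.10). It was also higher in T47D, by 0.20 (0.07), a call lost without siTLE3 1, 3 or 4 or siFOXA1 1, 2 or 3 (edgeR adjusted p = 0.1, 0.153, 0.0514, 0.114, 0.0882 and 0.0777). In T47D ESR1 and PGR were higher by 0.73 (0.10) and 0.54 (0.12). ERBB2 was lower in T47D and MDA-MB-453, at -0.44 (0.07) and -0.26 (0.05), and did not pass in SKBR3, at edgeR adjusted p = 0.389.

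Effects of siTLE3 differed between lines for 1983 of 16336 genes. In the order T47D, SKBR3 and MDA-MB-453, CREB3L1 changed by 2.80 (0.13), 0.03 (0.14) and 0.31 (0.07), the Hippo pathway gene AMOTL1 by 3.84 (0.12), 0.79 (0.21) and 0.95 (0.07), and the mitochondrial carrier SFXN2 by 2.18 (0.07), 0.43 (0.17) and 0.39 (0.09). KRT4, uncertain among keratins, had 5.66 (0.23), 0.02 (0.18) and 1.69 (0.51), and the sulfotransferase CHST15 -0.59 (0.09), 1.31 (0.17) and -0.67 (0.06). The largest edgeR adjusted p for a difference between lines among these 5 was 3.6e-07. The number called was 1318 without T47D siTLE3 3, 1311 without T47D siNS 2 and 1287 without T47D siNS 3. With DESeq2 it was 3206, and without both SKBR3 siTLE3 1 and siNS 3 it was 4361, in a fit added after the data were seen.

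Effects of siFOXA1 differed between lines for 5448 of 16138 genes. In the same order, the lysosomal gene TMBIM1 changed by 0.96 (0.07), -0.63 (0.09) and 2.58 (0.09), the ubiquitin ligase FBXO32 by 0.79 (0.07), 0.46 (0.10) and 3.26 (0.08), and the estrogen-induced KIAA1324 by 1.47 (0.07), -1.16 (0.12) and -2.33 (0.11). ASS1 changed by 0.66 (0.07), 0.08 (0.12) and 3.44 (0.08), and the netrin receptor UNC5B by 0.86 (0.11), 3.16 (0.12) and -0.19 (0.08). For the difference between lines, edgeR adjusted p was at most 5.84e-12 in these 5. ERBB2, GATA3 and TLE3 also differed (edgeR adjusted p = 4.1e-07, 1.23e-07 and 1.51e-06), while ESR1 did not (edgeR adjusted p = 0.571).

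Some genes answered alike in all 3 lines. Under siTLE3, 312 genes rose and 148 fell in every line of 12446 tested, where independent lists would give 19.7 and 12.3. In the order T47D, SKBR3 and MDA-MB-453, the membrane gene MPZL3 rose by 2.38 (0.10), 2.53 (0.25) and 2.01 (0.10) and the splicing assembly gene GEMIN5 by 1.90 (0.07), 1.79 (0.18) and 1.77 (0.11). SLC16A1 rose by 2.49 (0.15), 2.77 (0.39) and 2.30 (0.22), FAM105A by 3.34 (0.24), 2.71 (0.38) and 1.86 (0.36), and ANXA1 by 3.22 (0.17), 1.82 (0.27) and 1.99 (0.44). Of the 312 risen genes, 184 also rose under siFOXA1 in every line, MPZL3, GEMIN5, SLC16A1 and ANXA1 among them. For GEMIN5 the siFOXA1 log2 fold changes were 2.14, 1.83 and 1.69, so these rises are not particular to siTLE3. TLE3 itself, the sphingolipid gene SPTSSA, with -2.27 (0.07), -1.64 (0.17) and -1.63 (0.06), and DKFZP761J1410, with -2.10 (0.08), -1.41 (0.18) and -1.69 (0.07), fell in all. The hormone gene STC1 fell by 1.87 (0.10), 2.36 (0.46) and 1.70 (0.18) and PHTF2 by 2.18 (0.07), 1.44 (0.24) and 1.51 (0.08). In SKBR3 the call of STC1 was lost without siNS 1 or 2 or siTLE3 1, 2 or 3 (edgeR adjusted p = 0.0746, 0.0804, 0.0589, 0.0716 and 0.0827), and that of PHTF2 without siNS 2 or siTLE3 2 or 3 (edgeR adjusted p = 0.0598, 0.09 and 0.0579). The calls of SLC16A1, FAM105A and ANXA1 in SKBR3 were lost without siTLE3 2 (edgeR adjusted p = 0.051, 0.0531 and 0.0641). MPZL3, GEMIN5, SLC16A1 and STC1 hold AGCCTTA, and STC1 and PHTF2 hold GAGTACT. The 460 genes became 277, 76 and 230 without SKBR3 siTLE3 1, 2 and 3, and 195 and 168 without SKBR3 siNS 1 and 2. They numbered 756 with DESeq2 and 1699 without both SKBR3 siTLE3 1 and siNS 3, in the fit added later.

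Under siFOXA1, 531 genes rose and 473 fell in every line of 12434 tested, where independent lists would give 84.5 and 78.3. In the same line order, ANXA1 rose by 4.85 (0.14), 3.69 (0.17) and 6.81 (0.19), the carboxypeptidase CPA4 by 2.66 (0.14), 3.11 (0.12) and 3.90 (0.26), and CASP14 by 2.29 (0.23) and 2.5 (0.13) in T47D and SKBR3 and with the CPM ratio of 542 (185 to 2630) in MDA-MB-453. MPZL3 rose by 2.58 (0.09), 2.38 (0.16) and 2.29 (0.10), and KRT9, uncertain among keratins, by 3.71 (0.60) and 4.57 (0.32) in T47D and SKBR3 and at least 19.9-fold in MDA-MB-453, where siNS held none of its reads. RND1 fell by 3.12 (0.12), 3.16 (0.19) and 2.98 (0.14), the leukocyte integrin ITGAL by 3.77 (0.20), 3.17 (0.38) and 2.47 (0.66), and CDH13 by 4.0 (0.24), 3.43 (0.60) and 4.73 (0.43). The noncoding RP11-483P21.2, with -5.87 (0.25), -4.69 (0.59) and -4.18 (0.30), overlaps the end of CDH13 on the other strand, and with no strand setting stated for the counting its level is uncertain. FOXA1 completes the list. The largest edgeR adjusted p of these genes in any line was 0.00654. The 1004 genes became 510, 520 and 508 without SKBR3 siFOXA1 1, 2 and 3, and 1980 without SKBR3 siNS 3.

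Both siRNAs moved some genes alike in every line. Of 12188 genes tested in all 6 comparisons, 184 rose and 36 fell in each. The genes named here were chosen after their values were seen, by the largest smallest change. The siTLE3 and siFOXA1 log2 fold changes were 2.55 and 3.02 in T47D, 1.76 and 1.61 in SKBR3, and 2.03 and 2.00 in MDA-MB-453 for the membrane gene CMTM6. For the spliceosome gene SNRPB2 they were 1.78 and 1.86, 1.51 and 1.46, and 1.66 and 1.71. For the lamin gene LMNB1 they were 1.5 and 1.58, 1.97 and 2.91, and 1.51 and 1.25. The Hippo factor TEAD1, the p53 target RPS27L and the zinc finger gene ZNF268 also rose in each. ATP2A3, a calcium pump gene, fell with -1.85 and -1.20, -1.43 and -0.84, and -0.88 and -0.93, and INSIG2 of sterol regulation with -1.29 and -0.73, -1.10 and -1.14, and -0.97 and -1.84. CMTM6, TEAD1 and RPS27L hold AGCCTTA in their longest 3' UTR, and INSIG2 holds GAGTACT.

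**Figure D4:**
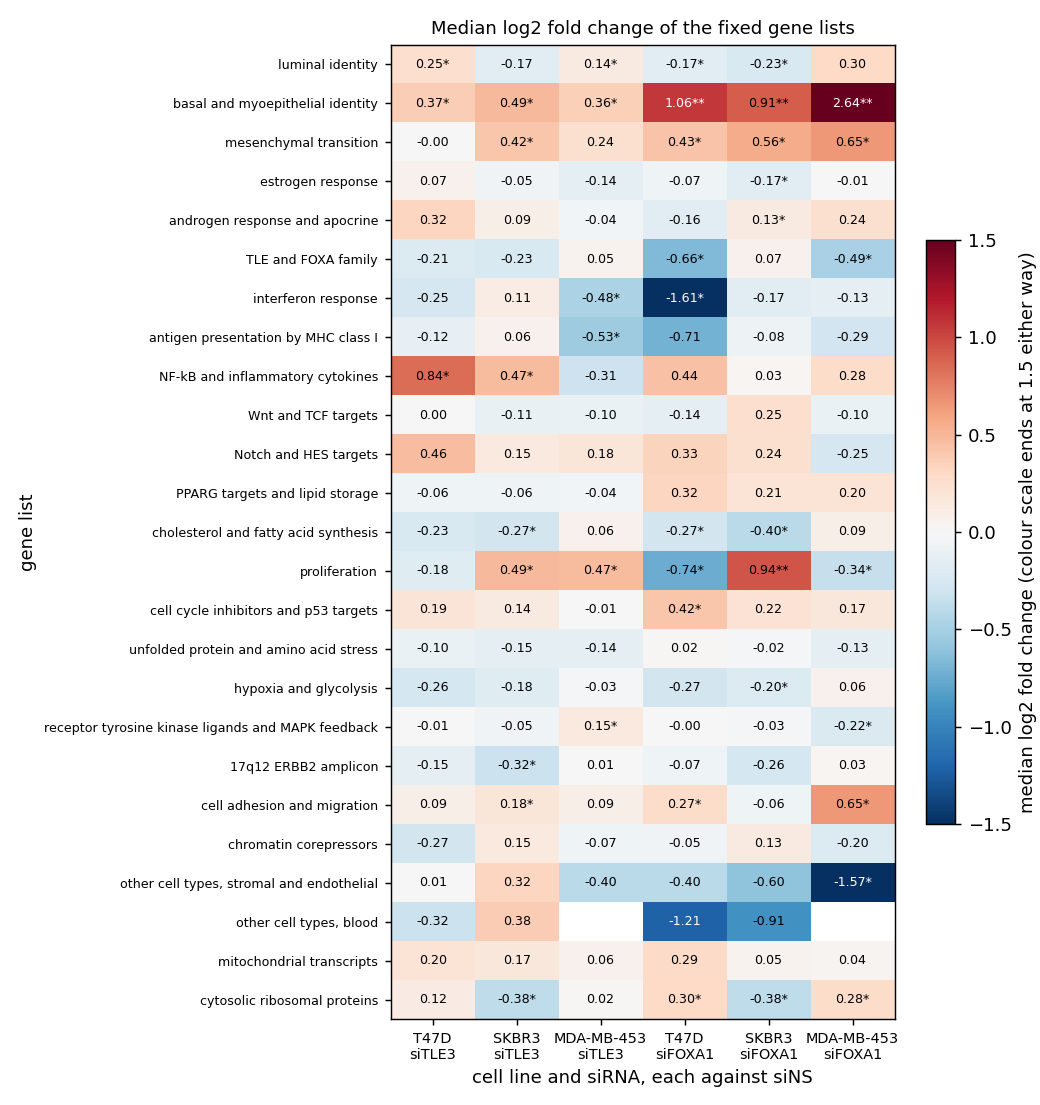
Median log2 fold change against siNS of each gene list (vertical) in each comparison (horizontal), with an asterisk where camera passed at the preset correlation and a double asterisk where it also passed with an estimated correlation. The basal list is raised in each line under siFOXA1, and blank fields were not tested.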

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

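The tests of SKBR3 siNS 3 for gene length and for depth were chosen only after the result was seen, as were the count of genes that hold any enriched word and the rules that a word p counts only if it also passes over the 4 gene sets searched and that absence of a word does not exclude a pool of siRNAs.

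Effects of siTLE3 differed between lines for 1983 genes by a test of the difference itself. The edgeR adjusted p was 4.16e-08 for CREB3L1, 2.63e-07 for AMOTL1, KRT4 and SFXN2, and 3.6e-07 for CHST15. With siRNA and siNS labels exchanged within lines, 2 of 50 draws, the real assignment included, gave as many genes, and the highest other draw gave 3831. That draw exchanged all T47D labels and kept all SKBR3 labels, which turns an effect shared by lines into a difference. Effects of siFOXA1 differed for 5448 genes, with 1 of 50 draws, the real one, as high and 3941 in the next draw, of the same kind. Here edgeR adjusted p was 3.36e-12 for TMBIM1, 5.84e-12 for FBXO32, KIAA1324, ASS1 and UNC5B, 4.1e-07 for ERBB2, 1.23e-07 for GATA3 and 1.51e-06 for TLE3. Both shares lie under 0.05, which argues against a chance assignment of siRNA labels. The exchange also removes the effect that lines share, so it does not test the difference between lines by itself.

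Under siFOXA1, the proliferation list rose in SKBR3 and fell in the other lines at the preset correlation, and neither fall passed with an estimated correlation (camera adjusted p = 0.39 in T47D and 0.85 in MDA-MB-453). The difference T47D minus SKBR3 had camera adjusted p = 3.4e-70 (0.0032 with an estimated correlation), and SKBR3 minus MDA-MB-453 had camera adjusted p = 1.5e-44 (0.0091 with an estimated correlation). Ribosomal protein genes differed between the same lines (camera adjusted p = 4.7e-11 and 1.1e-10, or 0.27 for both with an estimated correlation). In SKBR3 these genes stood high in siNS 3, which is weighed below. Differences of lists between lines were tested only for these lists under siFOXA1, in pairs of lines where they moved in opposite directions. The camera p was adjusted over those tests alone, so it does not allow for the choice of lists and lines.

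For each comparison of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. The real split alone gave as many genes, 1 of 10 in T47D siTLE3, T47D siFOXA1, SKBR3 siTLE3, SKBR3 siFOXA1, MDA-MB-453 siTLE3 and MDA-MB-453 siFOXA1 against siNS and in each line between the siRNAs. The highest of the other splits called 0 genes, against 814 to 8218 for the real splits.

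Both siRNAs raised 184 genes in all 3 lines, of which independent lines would give 4.04. Simulated libraries with no effect, siNS included, gave at most 0 such genes. Those draws called at most 7 genes in any comparison, so a low number was set by their design. They cannot weigh what chance values of the shared siNS libraries add where many genes are called. The 7-base word AGCCTTA lay in the 3' UTR of 88 of 180 searched genes of this set against 30.8 in matched sets, with a family-wise permutation p = 0.001, the smallest that 1000 draws can give, and 1156 holders outside the set stood higher than matched genes against siNS in every comparison, by at least 0.11. Off-target lowering by the siNS reagent through seed matches may therefore account for part of the set, and it would then also enter every comparison with siNS. Among genes lowered by siTLE3 alone, GAGTACT was the most enriched word (family-wise permutation p = 0.046, and 0.092 over the 4 sets), and 650 other holders were lower than matched genes in every test of siTLE3, by at least a log2 difference of -0.13, while among genes lowered by siFOXA1 alone no word passed (family-wise permutation p = 0.58). A further 5 words that overlap AGCCTTA passed in the same set, GCCTTAT, TAGCCTT, AAGCCTT, GCCTTAA and AGCCTTT (family-wise permutation p = 0.001, 0.001, 0.001, 0.002 and 0.012). Of the 180 genes 15 hold none of the 6 words, against 81 expected from genes of like UTR length and base composition. The words were picked by their enrichment in these same genes, so this shortfall adds no separate support. How many of the 184 genes rose in a response shared by loss of TLE3 and of FOXA1 stays open, since many genes would hold a word by chance. The sequences of the reagents were not used here, and other causes of a shared word were not tested.

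SKBR3 siNS 3 stood apart from its group, with 6675 genes called under siFOXA1 without it against 2746. A library of another line is argued against, since it correlated with its own group at r = 0.988 and with the nearest other line at 0.893. Lower depth is argued against by 22.4 × 1e6 reads, above the 20.6 × 1e6 of the next siNS library. Its deviation from the other siNS libraries followed gene length (rank correlation -0.495), with short genes higher. Trends of -0.333, -0.333 and -0.33 were also seen in T47D siTLE3 4, T47D siFOXA1 3 and SKBR3 siTLE3 3, so such a trend is not peculiar to siNS 3. The log2 fold changes of SKBR3 siTLE3 and siFOXA1 followed length as well (0.276 and 0.169), and without siTLE3 1 and siNS 3 these values were -0.00599 and -0.0188. In siNS 3, ribosomal protein genes stood 0.71 above the other siNS libraries. A trend with gene length, as from RNA or library preparation, may be the source, and the ribosomal list of SKBR3 siTLE3, which did not pass without siNS 3 (camera adjusted p = 0.19), may follow from it. That of SKBR3 siFOXA1 passed without siNS 3 (camera adjusted p = 0.0059). The step at which it arose stays open, and no biological explanation was tested.

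Multiciliated genes rose in T47D under siTLE3, and 5 of them were seen first (CDC20B, FOXJ1, FOXN4, RP1 and MCIDAS). Of 30 tested list members not seen first, 13 rose, among them CCNO by 2.72 (SE 0.08), named after its value was seen, and 1 fell, with median 0.47 (camera adjusted p = 0.0046 preset). A general rise of tested genes that were low in siNS is not excluded, since this median lay at percentile 96.7 of random lists matched on siNS level. Such a rise need not be a response of the cells, since genes nearly absent in siNS were tested only if they had siTLE3 reads. With an estimated correlation the camera adjusted p was 0.38, so a rise of the multiciliated programme as a set may hold but stays open. In the other comparisons 4 rose and 5 fell of 27 (T47D siFOXA1, camera adjusted p = 0.48), 0 and 1 of 19 (SKBR3 siTLE3, 0.34), 0 and 4 of 19 (SKBR3 siFOXA1, 0.08), 2 and 2 of 20 (MDA-MB-453 siTLE3, 0.6) and 1 and 4 of 20 (MDA-MB-453 siFOXA1, 0.6).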

How the results depend on the processing

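The fits without both SKBR3 libraries that stand apart (siNS 3 and siTLE3 1) and the lists without AGCCTTA genes were chosen after the data were seen. The target genes kept their call in all 52 alternative values. Of 6609 alternative values of named genes, 6125 kept direction and side of the threshold, 423 no longer passed and 61 newly passed, and none reversed.

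Requiring 2-fold left 1761, 2073, 470, 978, 519 and 1492 genes for T47D siTLE3 and siFOXA1, SKBR3 siTLE3 and siFOXA1, and MDA-MB-453 siTLE3 and siFOXA1, fewer by construction. It also left 683, 194 and 205 genes shared by both siRNAs in T47D, SKBR3 and MDA-MB-453 (5272, 513 and 3041 without it), and 95 and 148 genes called in all lines for siTLE3 and siFOXA1 (460 and 1004 without it). With DESeq2 the count was 1502 for SKBR3 siTLE3 (814 with edgeR), 865 shared in SKBR3, 756 in all lines for siTLE3, and 3206 for the siTLE3 effect by line (1983 with edgeR). A fit of 9 libraries gave 1962 and a replicate block 3698 genes for SKBR3 siTLE3, and the block gave 1038 shared in SKBR3. The cause was not tested. Whether replicate numbers pair the SKBR3 samples stays undecided. Deviations from group means had r of -0.0118 to 0.418 between same-numbered libraries against -0.386 to 0.228 between others. The highest were 0.311 for siTLE3 1 with siNS 1 and 0.418 for siTLE3 3 with siNS 3, but siTLE3 2 with siNS 2 had -0.00286, so not every library correlated best with its own number.

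Leaving out 1 library moved SKBR3 results most. Counts ranged from 107 to 762 for siTLE3, 1266 to 6675 for siFOXA1, 1336 to 5732 between the siRNAs, 87 to 632 shared, 76 to 457 for siTLE3 and 508 to 1980 for siFOXA1 in all lines, and 1287 to 2464 for the siTLE3 effect by line. Without both SKBR3 libraries that stand apart the counts were 4161, 6675, 2901 shared, 1699 and 1980 in all lines, and 4361 by line. RLE normalisation and omission of the low-count filter kept these counts within 1.5 times.

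Lists called with an estimated correlation numbered 0 for T47D siTLE3, 1 for T47D siFOXA1, 0 for SKBR3 siTLE3, 2 for SKBR3 siFOXA1, 0 for MDA-MB-453 siTLE3 and 1 for MDA-MB-453 siFOXA1, against 3, 10, 8, 9, 6 and 8 preset. For T47D siTLE3 it was 5 without the filter and 3 to 5 over libraries left out. Of 1567 alternative list results, 1473 were the same, 63 no longer passed and 31 newly passed. Without AGCCTTA genes the basal and the receptor kinase lists of MDA-MB-453 siTLE3 no longer passed (camera adjusted p = 0.096 and 0.29). Newly passing were the androgen response and antigen presentation lists of T47D siFOXA1 (camera adjusted p = 0.041 for both, from 0.2 and 0.055) and the hypoxia list of SKBR3 siTLE3 (camera adjusted p = 0.027, from 0.071).

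A replicate block was not run for T47D, for MDA-MB-453 against siNS or by line, since columns there carry no labelled replicate number, and a pseudocount was not needed for counts. At this depth and spread the simulated fits recovered 2.99% of genes changed 1.5-fold in SKBR3 siTLE3 and 11.9% in SKBR3 siFOXA1, so small changes there are mostly out of reach.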

Other observations

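The epidermal list and its tests were chosen after the rise of CASP14, IVL and keratin genes had been seen. Silencing of FOXA1 in MDA-MB-453 raised genes that belong to the outer skin, in a line with secretory and androgen-regulated features. An added list of epidermal differentiation genes, without the members seen first, was therefore tested in every comparison. In MDA-MB-453 under siFOXA1, 7 of its 11 tested genes rose and 1 fell, with median 1.16 (camera adjusted p = 0.0013 preset). With an estimated correlation the camera adjusted p was 0.38, so a rise of the epidermal programme as a set may be part of the response but stays open. In the other comparisons 6 rose and 3 fell of 16 (T47D siTLE3, median -0.08 with a test pointing up, camera adjusted p = 0.19), 9 and 4 of 17 (T47D siFOXA1, 0.073), 1 and 1 of 14 (SKBR3 siTLE3, 0.6), 3 and 1 of 13 (SKBR3 siFOXA1, 0.47), and 3 and 1 of 9 (MDA-MB-453 siTLE3, 0.11).

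Some TLE paralogs moved under siTLE3. TLE1 rose under siTLE3 in T47D and MDA-MB-453, by 0.67 (SE 0.06) and 0.60 (SE 0.06), and TLE4 rose in MDA-MB-453 by 1.17 (SE 0.07), while the short family member AES fell in T47D by 0.96 (SE 0.07) and in MDA-MB-453 by 0.75 (SE 0.07). In SKBR3 no paralog passed over all genes, but no difference between lines passed for TLE1, TLE4 or AES either (edgeR adjusted p = 0.36, 0.393 and 0.764). Whether the proteins of the paralogs replace that of TLE3 was not measured. CDK2 rose in each of the 6 comparisons with siNS, also where most other proliferation genes fell, by 2.54 (SE 0.13) and 1.56 (SE 0.15) in T47D, 1.98 (SE 0.20) and 1.85 (SE 0.18) in SKBR3, and 1.57 (SE 0.13) and 1.12 (SE 0.14) in MDA-MB-453 for siTLE3 and siFOXA1. Its longest 3' UTR lacks AGCCTTA but holds 4 of the 5 further words enriched in genes raised in all 6 comparisons (GCCTTAT, TAGCCTT, AAGCCTT and GCCTTAA). These words overlap in sequence and were picked in a set that includes CDK2, so holding them adds no separate support. An off-target part in the rise of CDK2 stays open.

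Proliferation genes moved apart between lines under siFOXA1, with medians of -0.74 in T47D, 0.94 in SKBR3 and -0.34 in MDA-MB-453. Under siTLE3 the medians were -0.18, 0.49 and 0.47.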
